A study of Mus musculus with 3 samples.

How the data were processed

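RXRA CUT&RUN was analysed in 3 libraries, 1 from HSC (10000 cells) and 2 from MPP (50000 cells each), all from C57BL/6 mouse bone marrow exposed to bexarotene at 1 mM for 1 h. Per the labels' protocols, cells were bound to concanavalin A beads, permeabilised with 0.025% digitonin, and incubated with an RXRA antibody diluted 1:50. They then received protein A fused to micrococcal nuclease at 700 ng per mL for 1 h, with digestion for 30 min, before paired-end sequencing. Per the labels, the genotype field names a Vav-Cre background and the growth protocol names floxed Rxra and Rxrb alleles, and both call the mice wild type.

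Per the submitters' processing notes the build is mm10, and the tools named are Trim Galore 0.4.2, cutadapt 1.9.1, Bowtie2 2.3.4.1 and MACS2 2.1.4. Their settings, the treatment of duplicate reads, and whether a control library entered the peak calling are not given in the sources used here. The deposited files hold 1 peak list per library in the 10-column narrowPeak layout, without a header, so replicates were called separately. The authors' deposited fold enrichment at the summit is a ratio of pileup to local background. The authors' deposited −log10 p and −log10 q values were taken as given, and the weakest q is 0.0995 in HSC, 0.0971 in MPP replicate 1 and 0.0993 in MPP replicate 2. The deposited score column is 10 times the −log10 q value as a whole number, checked on the values, and was not used further. No total read count is given, so depth was measured through the peaks. The fold and p of each peak were solved for a pileup and a local background, taking fold as pileup plus 1 over background plus 1 and p from a Poisson distribution. The pileup came out whole, to within 0.001 in −log10 p, for 99.98% of HSC peaks, 100% of MPP replicate 1 peaks and 99.99% of MPP replicate 2 peaks. The lowest recovered background in each list was taken as the genome-wide background. Intervals on pileups are exact Poisson and those on shares exact binomial (Clopper-Pearson, 95%), and both cover counting error only.

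Peak lists were compared by overlap of at least 1 bp, checked against bedtools 2.31.1. The level expected by chance came from 100 random placements of the peaks on their own chromosomes. Genes came from a RefSeq table of the same build, with 21900 protein-coding genes on named chromosomes. The table used here gives gene starts and ends without strand, exons or transcripts, so the planned window around transcription start sites became 1 kb around either end of a gene, and a peak at the end of transcription counts like one at the start. A peak's location was taken from its summit, and a gene was called marked where a peak overlapped its window. The genome sequence was not used here, so the 17 planned motifs, their alternatives and random lists matched on GC content were not run. Gene lists, 21 in number, were fixed before the data were examined, and 445 of their 446 distinct genes were found in the table. The number marked in each list was set against 10000 random lists of protein-coding genes of the same size, and the percentile is the percent of random lists with fewer marked genes. It describes these libraries and is not a p-value.

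Named genes were chosen by a rule fixed before the data were examined. It takes the 10 genes of highest HSC fold among those marked in all 3 libraries, the 10 of highest HSC fold among those marked in HSC alone, and the 10 with the best worse rank among those marked in both MPP libraries and not in HSC. It adds up to 4 genes per list, by the number of libraries, then HSC fold, then MPP replicate 1 fold, and Rxra, Rxrb and Myc always. Genes on the mitochondrial and Y chromosomes and unplaced contigs were left out of the rule. Genes named outside it are the 10 after removal of the 1% of peaks of highest fold, the MYC targets marked in all 3 libraries, Hlf and Tal1, and neighbours that share a peak, all chosen after their values were seen.

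For the comparison of list lengths, each MPP pileup and its local background were scaled to the HSC background, and the chance that a Poisson draw would pass the lowest −log10 p of the HSC list was summed over peaks. On simulated libraries this gave an expected count 0.984 times the true one with all sites present, and 1.97 times where so many sites were absent that 2 was true. The simulated sites had a flat background and mostly lay well above the threshold, so weak peaks near it were hardly tested. Between the real MPP libraries a replicate 2 counterpart was expected for 61.1% of replicate 1 peaks and seen for 44.9%. On simulated gene lists, 3% of 200 unchanged lists and 100% of 200 changed lists passed the upper bound of the central 95%. The changed lists were given a large excess of marked genes, so the 100% does not measure how often a smaller excess would pass. Alternatives were a stricter q of 1e-05, the peaks of highest fold up to the length of the HSC list, 50% coverage or a gap of 1 kb as overlap, windows of 500 bp and 5 kb, the nearest gene end within 50 kb, removal of mitochondrial, Y and unplaced peaks with the 1% of highest fold, ranking by q, and leaving out each MPP library. Added after seeing the data were moving peaks by 10 to 50 kb, removing the 1% of highest fold from the gene counts, random lists matched on gene length or on MPP fold (the latter also for gene families and for MYC targets without Hspe1), the stricter q and equal list lengths for the gene lists, binomial thinning, and thresholds for thinning at the 5th, 10th and 25th percentile of the −log10 p of the thinner list, above which peaks were counted on both sides. The simulated libraries used 1 threshold for all peaks, so they do not test its choice. The analysis used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.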

Results

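The series asked where the retinoid X receptor RXRA, a nuclear receptor that binds DNA with partner receptors, sits on chromatin in mouse blood stem and progenitor cells. Its title ties the receptor to stem cell fitness, quiescence and the MYC pathway. The 3 libraries were made by CUT&RUN, in which an antibody directs a nuclease to its target and the released DNA is sequenced. The HSC library came from 10000 haematopoietic stem cells (HSC), sorted as lineage-negative, cKit-positive, Sca1-positive, CD48-negative and CD150-positive. The 2 MPP libraries came from 50000 multipotent progenitors (MPP) each, sorted as lineage-negative, cKit-positive, Sca1-positive and CD150-negative. Cells were pooled from 3 or 4 mice of about 10 months and were exposed for 1 h to bexarotene, a drug that activates RXR, at 1 mM per the labels. All libraries carry the drug, so the effect of the drug is not analysed here, and no library with a control antibody was used here. With 1 HSC library there is no replicate check of any difference between HSC and MPP, and no p-value is given.

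RXRA peaks numbered 4047 in HSC, 29848 in MPP replicate 1 and 19570 in MPP replicate 2. They covered 1.43, 9.83 and 7.13 Mb of the mm10 genome. The median fold enrichment that the authors' peak caller gave was 5.50 in HSC, 4.39 in MPP replicate 1 and 5.65 in MPP replicate 2, and it is used here only to rank peaks within a list. The genome-wide background recovered from these values was 0.604 fragments in HSC, 2.87 in MPP replicate 1 and 1.08 in MPP replicate 2, so the MPP libraries were 4.75 and 1.79 times as deep by this measure. The lowest pileup that was called a peak was 5 fragments in HSC, 10 in MPP replicate 1 and 6 in MPP replicate 2, or 8.28, 3.48 and 5.55 times background. The lowest signal that could be called was thus higher in HSC than in either MPP library.

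The 2 MPP libraries shared a large core of sites: 13404 of the 29848 replicate 1 peaks (44.9%, 95% exact binomial interval 44.3 to 45.5) overlapped a replicate 2 peak by at least 1 bp, and 68.1% of the replicate 2 peaks (67.4 to 68.7) overlapped a replicate 1 peak. Random placement on the same chromosomes gave 0.589% and 0.907%. Genes whose ends were among the most highly ranked in both libraries, without an HSC peak, included Orc5, a subunit of the origin recognition complex, Haus5, an augmin subunit of the spindle, and Gle1, an mRNA export factor. Sharing rose with peak strength, from 22.3% in the lowest of 5 equal bins of replicate 1 peaks by fold to 77.3% in the highest bin, and from 50.5% to 89.3% for replicate 2. The labels do not say whether the 2 libraries came from separate pools of mice, and all intervals cover counting error only. Peak names of HSC and MPP replicate 1 share a tag that those of replicate 2 lack, so a batch between the MPP libraries is not ruled out.

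Most HSC peaks lay at sites that were also peaks in MPP. Of the 4047 HSC peaks, 70.8% (69.4 to 72.2) overlapped a peak of MPP replicate 1 and 76.1% (74.7 to 77.4) a peak of MPP replicate 2. A counterpart in either MPP library was present for 85.2% (84.1 to 86.3) and in both for 61.6% (60.1 to 63.1), against 1.11% for randomly placed peaks. In the other direction only 9.75% (9.42 to 10.1) of MPP replicate 1 peaks and 15.9% (15.4 to 16.4) of replicate 2 peaks had an HSC counterpart. Peaks that the 2 MPP libraries shared were found in HSC more often: 18.8% (18.2 to 19.5) of replicate 1 peaks that replicate 2 also held, against 2.37% (2.14 to 2.61) of those it did not. The 85.2% depends on the length of the MPP lists. When each MPP list was held to its 4047 peaks of highest fold, HSC overlapped either in 39.4% of peaks, replicate 1 in 23.8% (22.5 to 25.1) and replicate 2 in 32.1% (30.7 to 33.6), while the MPP libraries overlapped each other in 43.9% (42.4 to 45.5).

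**Figure D1:**
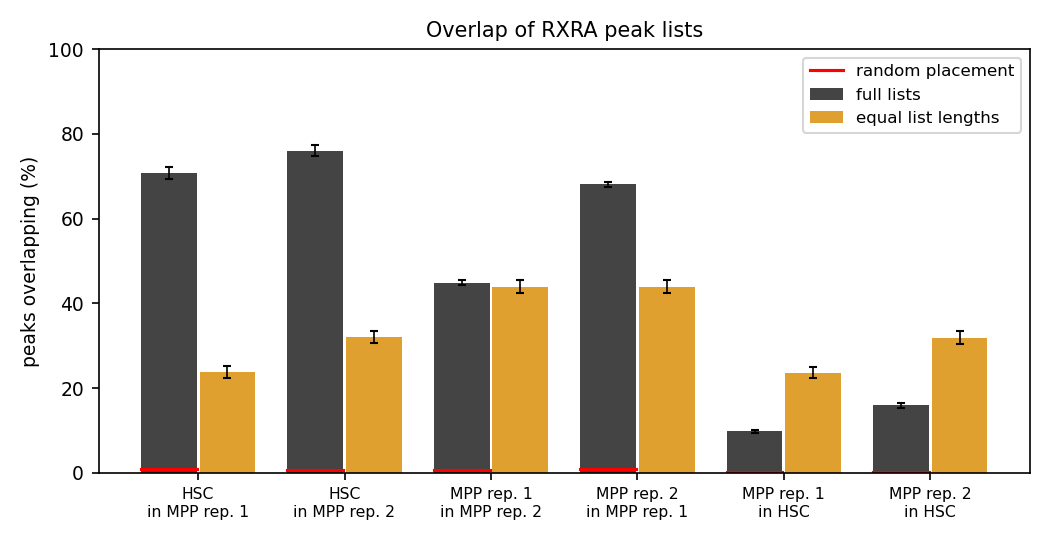
Percent of the peaks of 1 library (first name) that overlap a peak of another (second name) by at least 1 bp, for the full lists (grey) and for the 4047 peaks of highest fold in each list (orange). Black lines are 95% exact binomial intervals and red lines the mean of 100 random placements of the full lists; at equal length the MPP pair overlapped in 43.9%, HSC and MPP in 23.6% to 32.1%.

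HSC peaks of higher fold had an MPP counterpart more often, 93.8% (91.9 to 95.4) in the highest of 5 bins against 78.9% (75.9 to 81.7) in the lowest. The same held for MPP peaks with an HSC counterpart, which rose from 4.56% to 20.5% across bins of MPP replicate 1 and from 8.64% to 32.1% across bins of replicate 2. Thinning the MPP pileups to the HSC background, with the same signal over background and the HSC threshold, gave an expected 9670 calls in HSC from replicate 1 and 14369 from replicate 2, against the 4047 observed. The same procedure applied to replicate 1 at the depth of replicate 2 gave 18228 calls against 19570 observed. It expected a replicate 2 counterpart for 61.1% of replicate 1 peaks, and 44.9% had one. With replicate 2 scaled up to the depth of replicate 1, 99.9% of its peaks were expected to have a counterpart and 68.1% did. The procedure thus expected more sharing than was seen between the MPP libraries too. The expected calls depend on the threshold: only 58 HSC peaks had the lowest pileup called. With the threshold at the 25th percentile of the −log10 p of the named library, expected over observed peaks went from 2.39 to 0.99 for replicate 1 in HSC, from 3.55 to 2.86 for replicate 2 in HSC, and from 0.93 to 0.40 for replicate 1 in replicate 2. The procedure was chosen after the files were seen and before its values were, and the raised threshold after them.

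**Figure D2:**
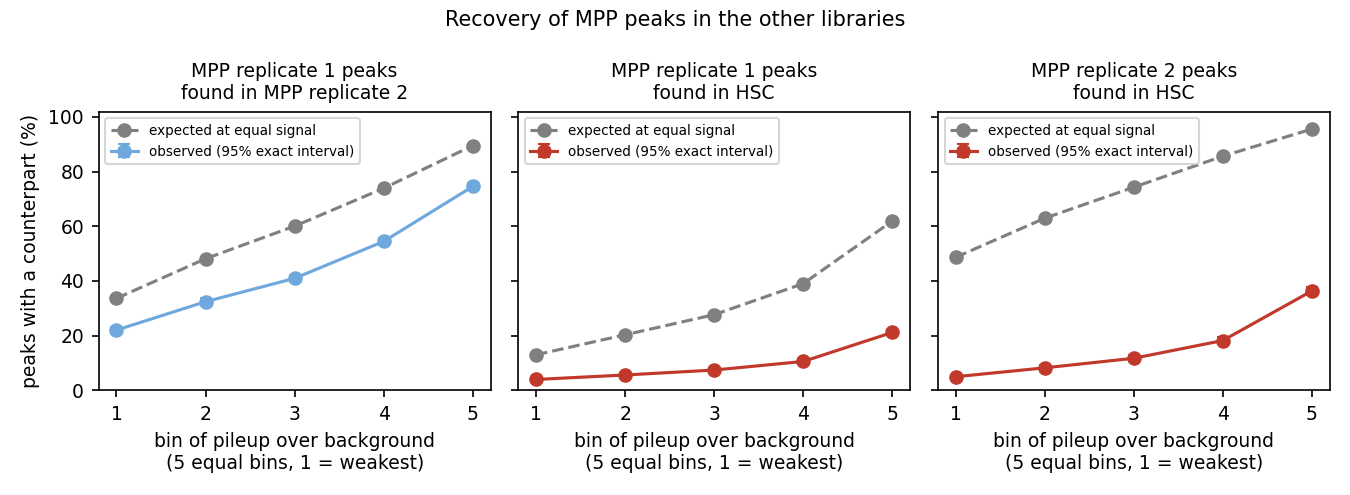
Percent of MPP peaks with a counterpart in the named library (y axis) by 5 equal bins of the MPP pileup over background (x axis, 1 weakest). Grey is the percent expected after thinning at equal signal over background, with the weakest call as threshold, colour the observed percent with its 95% exact binomial interval; in the highest bin 61.9% was expected and 21.2% observed for MPP replicate 1 in HSC, 95.6% and 36.4% for MPP replicate 2 in HSC, and 89.5% and 74.6% between the MPP libraries.

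RXRA peaks were concentrated at gene ends in all 3 libraries. The peak summit lay within 1 kb of an end of a protein-coding gene for 36.3% of HSC peaks (34.8 to 37.8), 29.0% of MPP replicate 1 peaks (28.5 to 29.5) and 36.2% of MPP replicate 2 peaks (35.5 to 36.8), where random placement gave 3.26%, 3.23% and 3.26%. A further 29.8%, 37.5% and 33.7% lay elsewhere inside a protein-coding gene, and 26.2%, 25.6% and 22.8% lay between genes, where random placement gave 49.8%, 49.6% and 49.7%. Which end is the start of transcription, and whether a peak is exonic or intronic, was not determined here. Shared sites were at gene ends more often than unshared ones. The share was 37.7% (35.8 to 39.7) for HSC peaks found in both MPP libraries and 14.6% (11.8 to 17.7) for the 597 found in neither. It did not rise steadily with sharing, being higher for HSC peaks found in only 1 MPP library than for those found in both. For MPP replicate 1 it was 39.7% for peaks also in replicate 2 and 20.3% for the others.

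Of 21900 protein-coding genes, 1797 had a peak within 1 kb of an end in HSC, 9022 in MPP replicate 1 and 7874 in MPP replicate 2. Both MPP libraries marked 6327 genes, of which 1276 (20.2%) were also marked in HSC, and 96.4% of the HSC genes were marked in at least 1 MPP library. In 1145 of the 1276 (89.7%, 87.9 to 91.3) an HSC gene-end peak itself overlapped a peak of both MPP libraries, with Mnt, Ndufaf4 and Mylpf among the exceptions. Ranked by HSC fold, the genes marked in all 3 libraries were led by Wls, which carries Wnt proteins to the cell surface, Oasl1, an interferon-induced gene, Lars2, the mitochondrial leucyl-tRNA synthetase, Asmt, an enzyme of melatonin synthesis, and Gm32584. Pkd2l1, an ion channel gene, Arrdc2, Cpt2, Pbx4 and 1810062G17Rik followed, the last sharing its peak with Anxa5. The peaks at Wls, Oasl1 and Lars2 belong to the 1% of HSC peaks with the highest fold. That 1%, 40 peaks of fold 20.3 to 35.2, lay at a gene end in 7.5% (1.57 to 20.4), against 36.6% of the other HSC peaks, and all 40 recurred in both MPP libraries. Leaving out this 1% from each list, an alternative chosen after seeing the data, removed Wls, Oasl1, Lars2, Asmt, Pkd2l1 and Cpt2 from the leading 10. It kept Gm32584, Arrdc2, Pbx4 and 1810062G17Rik, and added Anxa5, Inpp5a, Hspbp1, Mylpf, Psmc6, a proteasome subunit, and Aco1, an iron-regulated aconitase. The MPP folds of Gm32584, 8.53 and 14.7, exceed those of the removed Pkd2l1, 7.09 and 13.2. Gm32584 thus stayed through a weaker peak in at least 1 MPP library.

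Cpt2 handles long-chain fatty acids at the inner mitochondrial membrane. Its peak covered the upper end of the gene on chromosome 4, from 107923481 to 107923808 in HSC, with a fold of 9.87 and a pileup of 16 fragments (exact Poisson interval 9.15 to 26.0). In MPP replicates 1 and 2 the fold was 9.63 and 9.70, with pileups of 40 (28.6 to 54.5) and 25 (16.2 to 36.9).

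Genes marked in both MPP libraries and not in HSC numbered 5051. By the worse of their 2 ranks they were led by Orc5, Haus5, Serhl, Gle1, Cenpk and Ppwd1, which share 1 peak, Nup54, a nuclear pore subunit, Ccdc180, Naf1, an assembly factor for small nucleolar particles, and Iqcb1, a gene of the primary cilium. At Orc5 the fold was 12.9 in MPP replicate 1 and 16.2 in replicate 2, with pileups of 49 (36.3 to 64.8) and 41 (29.4 to 55.6). Genes marked in HSC alone numbered 65. They were led by Lrtm2, Cubn, a receptor for vitamin B12 uptake, Derl3, Ppp1r21, Rtn4rl2, Trim30a, Rec8, a meiotic cohesin subunit, Gm21149, Svip and BC005537. The fold of these 10 in HSC was 6.45 to 7.19 and the pileup 10 to 20 fragments. The HSC-only count was 139 without MPP replicate 1, 447 without MPP replicate 2 and 994 with each MPP list held to 4047 peaks, at which length 316 genes were marked in all 3 libraries. A further 382 genes were marked in HSC and MPP replicate 2 and not in replicate 1, and 74 in HSC and replicate 1 and not in replicate 2.

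Of the 21 lists fixed before the data were examined, the genes that MYC activates were marked at the highest rate in HSC, with ribosomal protein genes next at 30.0% (14.7 to 49.4) and overlapping intervals. Of 52 MYC target genes, 20 had a gene-end peak in HSC (38.5%, 25.3 to 53.0), 38 in MPP replicate 1 (73.1%, 59.0 to 84.4) and 46 in MPP replicate 2 (88.5%, 76.6 to 95.6). The median of 10000 random lists of 52 genes was 4, 21 and 19, and no random list reached the observed number in any library. The 16 marked in all 3 libraries were Cbx3, Farsa, Hspd1, Hspe1, Mcm4, Mcm5, Ndufaf4, Noc4l, Nop16, Nop2, Pa2g4, Ppan, Rabepk, Tfb2m, Utp20 and Wdr74. Ppan, a ribosome assembly factor, had a fold of 7.70 in HSC, with a pileup of 12 (6.20 to 21.0), and folds of 8.52 and 11.9 in MPP replicates 1 and 2. Mcm5, part of the replicative helicase, had a fold of 7.13 in HSC and of 4.59 and 5.19 in MPP. Hspd1 and Hspe1, mitochondrial chaperones, share 1 peak in every library and count as 2 of these genes. Cbx3, a heterochromatin protein, shares its peak with Hnrnpa2b1, and Tfb2m, a mitochondrial transcription factor, with Cnst. All list counts are descriptions of these libraries and not tests of cell types.

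The MYC network itself is made up of the transcription factors that pair or compete with MYC and their regulators. Of 16 such genes, 4 had a gene-end peak in HSC, 8 in MPP replicate 1 and 8 in MPP replicate 2, at percentiles 96.5, 67.4 and 81.5 of random lists. Fbxw7, which targets MYC for degradation, and Mnt, a repressor that pairs with MAX, were marked in all 3 libraries. Mxd1 and Mxd4, which compete with MYC for MAX, were marked in HSC and MPP replicate 2 and not in MPP replicate 1. The Mxd4 peak had a fold of 7.53 in HSC, with a pileup of 13 (6.92 to 22.2), and of 9.01 in MPP replicate 2. Myc, on chromosome 15 from 61985341 to 61990361, had no peak within 1 kb of either end. MPP replicate 1 had a peak inside the gene from 61987493 to 61987868 with a fold of 3.57, and MPP replicate 2 a peak outside it from 61983368 to 61983727 with a fold of 4.69. No HSC summit lay within 50 kb of Myc, the nearest being 179261 bp away.

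Genes of protein synthesis and respiration were also marked widely in MPP. Of 30 ribosomal protein genes, 9 were marked in HSC, 23 in MPP replicate 1 and 27 in MPP replicate 2, at percentile 99.98 of random lists in HSC and above every random list in both MPP libraries. Rpl4, whose peak also lies at Snapc5, Rps14, Rplp1 and Rps6 were among the 6 marked in all 3. With peaks of q at or below 1e-05, chosen after seeing the data, the HSC percentile of this list was 54.4, and that of the MYC targets 99.7. That filter left 1180 HSC peaks, so few genes of a 30-gene list could be marked and the percentile is coarse. The 54.4 therefore does not show that the ribosomal list lost its excess. Of 30 oxidative phosphorylation genes, 4 were marked in HSC, 22 in MPP replicate 1 and 21 in replicate 2, at percentiles 77.5, 99.9 and 99.99. The 4 were Sdhc, Ndufa4, Ndufb5 and Atp5j, each with a peak that also reaches a neighbouring gene. With the nearest gene end within 50 kb, MPP replicate 1 stood at 94.2 for the ribosomal list and 88.2 for oxidative phosphorylation, and replicate 2 at 99.98 and 98.9. When each MPP list was held to 4047 peaks, the MYC targets alone of the 21 lists stood above the central 95% of random lists in MPP, at percentiles 98.6 and 100.

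**Figure D3:**
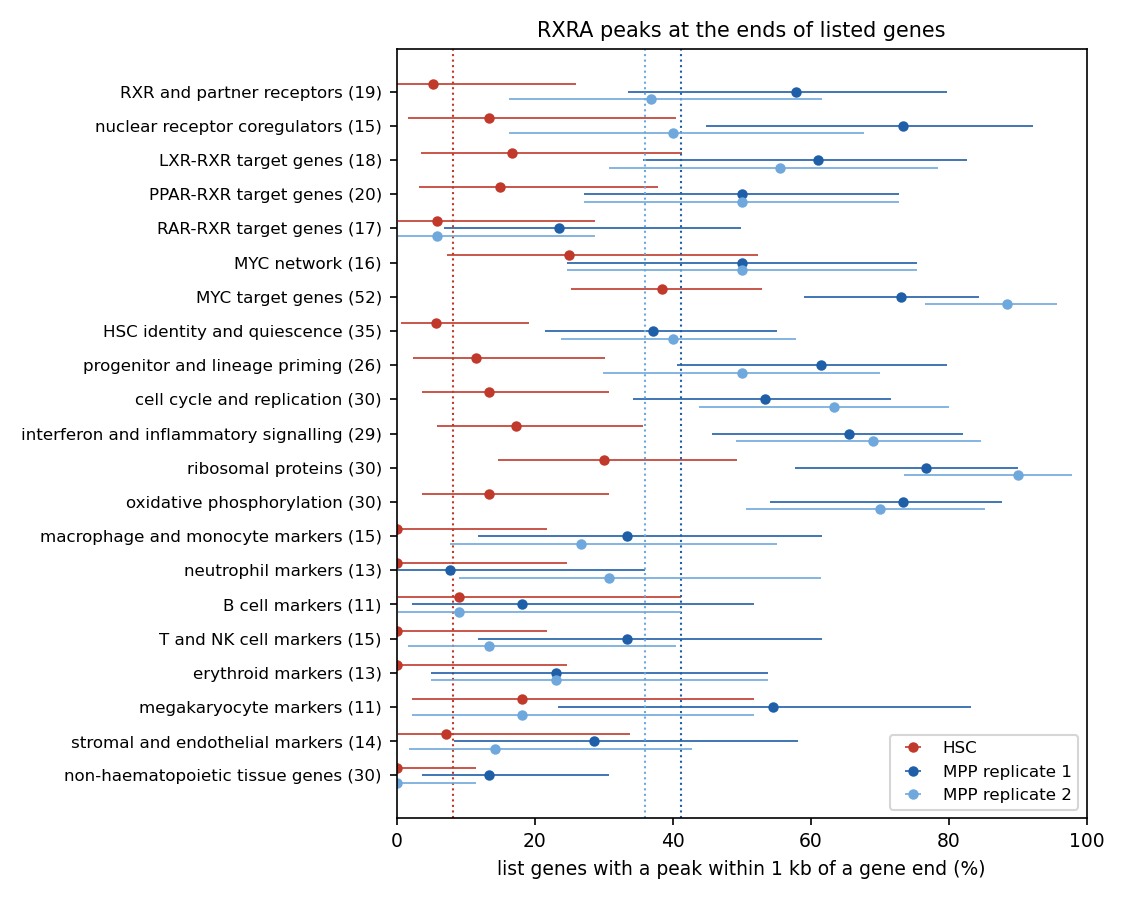
Percent of the genes of each list (list size in brackets) with a peak within 1 kb of either gene end, in HSC (red), MPP replicate 1 (dark blue) and MPP replicate 2 (light blue), with 95% exact binomial intervals. Dotted lines give the percent of all protein-coding genes in each library; the MYC target genes stand at 38.5%, 73.1% and 88.5%.

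Interferon and inflammatory genes were marked above the central 95% of random lists in both MPP libraries, and cell cycle genes in MPP replicate 2. Of 29 interferon and inflammatory genes, 19 were marked in MPP replicate 1 and 20 in replicate 2, at percentiles 99.1 and 99.9, and 5 in HSC at percentile 91.4. The HSC percentile was 99.6 with the 5 kb window and 99.98 with the nearest gene end within 50 kb, and that of MPP replicate 1 was 74.8 with q at or below 1e-05, chosen after seeing the data. The interferon receptor genes Ifngr1 and Ifnar2 and the signal transducer Stat2 were marked in all 3 libraries, and Stat3 in HSC and MPP replicate 2. Of 30 cell cycle and replication genes, 16 and 19 were marked in MPP, at percentiles 87.7 and 99.8, and 4 in HSC at percentile 77.1. Pcna, the replication clamp, Cdt1, which licenses origins, and Mcm7 were marked in all 3, and E2f3 in HSC and MPP replicate 2. With the MPP lists held to 4047 peaks these percentiles were 6.43 and 93.0 for the interferon list, and 24.7 and 3.75 for the cell cycle list.

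RXR, its partner receptors and their known target genes lay within the central 95% of random lists, except the coregulators in MPP replicate 1 and the RAR targets in MPP replicate 2. Of 19 receptor genes, 1 was marked in HSC, 11 in MPP replicate 1 and 7 in replicate 2, at percentiles 19.7, 88.9 and 43.6. Nr1h2, which encodes LXR beta, was the 1 marked in all 3. Its HSC peak also lies at Pold1 and overlapped a peak of both MPP libraries, whose strongest peaks lay at the other end of Nr1h2. Vdr, the vitamin D receptor, Nr1h3, which encodes LXR alpha, and Nr4a2 were marked in both MPP libraries. Of 15 coregulator genes, 2, 11 and 6 were marked, at percentiles 65.4, 98.7 and 53.6, with Tbl1x in all 3. Of 18 LXR target genes, 3, 11 and 10 were marked, at percentiles 81.2, 92.7 and 93.0. The cholesterol exporters Abca1 and Abcg1 and the phospholipid enzyme Lpcat3 were marked in all 3, Abca1 with a fold of 7.08 in HSC. Of 20 PPAR target genes, 3, 10 and 10 were marked, at percentiles 77.4, 71.4 and 85.8, with Cpt2, Acadm and Ucp2 in all 3 and Cpt1a in both MPP libraries. RAR target genes stood low, with 1, 4 and 1 of 17 marked, at percentiles 23.2, 3.73 and 0.06, Meis1 being the 1 gene marked in both MPP libraries and Nrip1 the 1 marked in HSC.

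Rxra, on chromosome 2 from 27676445 to 27763319, carried a peak inside the gene in all 3 libraries, at 27740320 to 27740597 in HSC, with a fold of 4.99 and a pileup of 7 fragments. The overlapping peak ran from 27740133 to 27740639 with a fold of 6.87 in MPP replicate 1, and from 27740288 to 27740612 with a fold of 8.48 in replicate 2. Rxrb, on chromosome 17 from 34031812 to 34038403, had no peak inside it or within 1 kb in any of the 3.

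HSC identity genes were not marked more often in HSC than random lists. Of 35 genes, 2 were marked in HSC, 13 in MPP replicate 1 and 14 in replicate 2, at percentiles 20.2, 25.3 and 63.8. Egr1, an early response factor, was marked in HSC and MPP replicate 2. Foxo1, Kit, Hlf, Tal1 and Meis1 were among the 9 marked in both MPP libraries, none of which was marked in HSC. Lists matched on MPP fold, a comparison chosen after seeing the data, had a median of 2 marked in HSC. Of those lists 12.8% had none either, so the absence lies within the range of random lists. Of 26 progenitor and lineage genes, 3, 16 and 13 were marked, at percentiles 63.6, 97.0 and 90.0. Tcf4, Tcf3 and Spi1, which encodes PU.1, were marked in all 3, and Flt3, a receptor of lymphoid-primed progenitors, in both MPP libraries with folds of 8.45 and 7.27.

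No list of markers of mature blood cells or other tissues stood above the random median in any library, except the megakaryocyte list, with 2 against 1 in HSC and 6 against 5 in MPP replicate 1. In HSC, 0 of 15 macrophage and monocyte genes, 0 of 13 neutrophil genes, 0 of 15 T and NK cell genes, 0 of 13 erythroid genes and 0 of 30 non-haematopoietic genes had a gene-end peak, the last with an upper exact limit of 11.6%. HSC marked 1 of 11 B cell genes, Ms4a1, the megakaryocyte genes Nfe2 and Gp9 of 11, and 1 of 14 stromal and endothelial genes, Kdr. MPP replicates 1 and 2 marked 5 and 4 macrophage genes, Cx3cr1, Cd68 and Lyz2 in both, 1 and 4 neutrophil genes, 2 and 1 B cell genes, 5 and 2 T and NK genes, and 3 and 3 erythroid genes, Tfrc in both. MPP replicate 2 marked 2 megakaryocyte genes, and the MPP libraries marked 4 and 2 stromal genes. Of the 30 non-haematopoietic genes, MPP replicate 1 marked Snap25, Mbp, Slc17a7 and Apoa1, and MPP replicate 2 none, against medians of 12 and 11 in random lists.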

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

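Of 156 alternatives, 94 left the result unchanged by the rules set for each. For the main counts and shares, however, 41 alternatives changed the result and 27 did not. The other 67 unchanged concern percentiles of single lists and families, and the thinning. The gene-length matching, the 50 kb shift, the q filter and equal lengths for the gene lists, the matching on MPP fold, its use for gene families and without Hspe1, and the raised thresholds for thinning were chosen after the results were seen. The cause of each change was not tested, except where the alternative itself shortens a list or widens a window. Peaks of q at or below 1e-05 numbered 1180 in HSC, 15971 in MPP replicate 1 and 11816 in MPP replicate 2. With that filter the MPP lists overlapped in 45.5% of replicate 1 and 61.4% of replicate 2 peaks, HSC overlapped either MPP list in 86.8%, and the gene-end share was 30.3% in HSC and 41.4% in MPP replicate 2. With 50% of the peak covered, the overlaps were 43.5% and 64.8% between the MPP libraries and 82.7% for HSC. A gap of 1 kb gave 87.0% for HSC, and removing mitochondrial, Y, unplaced and highest-fold peaks gave 83.4%. At the length of the HSC list, the MPP lists overlapped in 43.9% either way and HSC overlapped either in 39.4%. At that length 1933 genes were marked in MPP replicate 1, 2219 in replicate 2, 316 in all 3 libraries and 994 in HSC alone. Leaving out 1 MPP library at a time gave 70.8% to 76.1% of HSC peaks shared, 1350 to 1658 genes marked in all the remaining libraries, and 139 to 447 marked in HSC alone. Moving HSC peaks by 10 to 50 kb in place of random placement gave 2.93%. The 500 bp window gave 33.3% of HSC peaks at gene ends, and the 5 kb window 46.6% in HSC, 44.2% in MPP replicate 1 and 49.3% in MPP replicate 2. The 5 kb window gave 2030 genes marked in all 3 libraries, and the nearest gene end within 50 kb gave 2391, with 2897 marked in HSC. Lists above the central 95% of random lists, 2 in HSC and 5 in each MPP library, became 4 in HSC and 8 in MPP replicate 2 with the 5 kb window, and 5 and 8 with the nearest gene end. With q at or below 1e-05 they were 1 in HSC and 3 in MPP replicate 1, with matching on MPP fold 1 in HSC, and at equal list length 1 in each MPP library. The MYC targets stayed above the central 95% in each library under every alternative run there, with a lowest percentile of 98.6. At equal list length the interferon list of MPP replicate 1 went from percentile 99.1 to 6.43, and the cell cycle list from 87.7 to 24.7 in replicate 1 and from 99.8 to 3.75 in replicate 2. Ribosomal protein genes in HSC fell from 99.98 to 54.4 with the stricter q and to 69.4 with matching on MPP fold. With 1180 HSC peaks left by the stricter q, the 54.4 lies near the floor for a list of this size and does not show a lost excess. Raising the threshold for thinning to the 5th, 10th and 25th percentile of the HSC −log10 p took expected over observed HSC peaks from 2.39 to 1.46, 1.21 and 0.99 for MPP replicate 1, and from 3.55 to 3.01, 2.93 and 2.86 for replicate 2. No paired analysis was possible because there is 1 HSC library, so the groups share fewer than 2 replicate numbers.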

Other observations

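Gene families outside the fixed lists, defined by symbol after the files were seen but before their values, included several of protein synthesis with many marked genes. Mitochondrial ribosomal protein genes were marked in 15 of 78 in HSC, 60 in MPP replicate 1 and 55 in MPP replicate 2, at percentile 99.8 of random lists in HSC and above all random lists in MPP. Aminoacyl-tRNA synthetase genes, which charge tRNAs, were marked in 7, 28 and 27 of 34, at percentiles 98.3, 100 and 100, and translation initiation factor genes in 10, 34 and 39 of 56, at percentiles 98.6, 99.8 and 100. Proteasome subunit genes were marked in 6, 28 and 27 of 40, and RNA polymerase subunit genes in 3, 22 and 22 of 28, at percentiles 89.4 and 58.9 in HSC and at or above 99.98 in both MPP libraries. Replication-dependent histone genes were marked in 47 and 49 of 57 in the MPP libraries, above all random lists, and in 3 in HSC, at percentile 14.7, or 3.4 of lists matched on MPP fold, both within the central 95%. Zfp zinc finger genes were marked in 224 and 203 of 397 in MPP, above all random lists, and in 30 in HSC, at percentile 29.2. Of the 164 marked in both MPP libraries 23 were marked in HSC, against a median of 32 in lists matched on MPP fold. That is percentile 1.87, with 3.22% of matched lists at or below it, so some difference between gene classes may remain after matching. Such genes often lie in clusters, where 1 peak can mark several. Solute carrier genes were marked in 41, 176 and 135 of 375, at percentiles 95.9, 98.5 and 48.9.

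Large families of sensory receptor genes were almost free of peaks. Of 1110 olfactory receptor genes, 0 were marked in HSC (upper exact limit 0.332%), 3 in MPP replicate 1 and 3 in MPP replicate 2, against random medians of 91, 457 and 399. Vomeronasal receptor genes were marked in 0, 3 and 1 of 355, keratin genes in 0, 6 and 0 of 53, and Hox genes, some of which act in blood stem cells, in 0, 4 and 2 of 39. Peaks overlapped 1.86% of 430 tRNA genes in HSC, 11.6% in MPP replicate 1 and 16.3% in MPP replicate 2, against 2.07%, 2.48% and 2.63% for random placement. This random share hardly followed list length, unlike that of snRNA genes (0.0767%, 0.504% and 0.333%). Placement kept the 3, 11 and 13 mitochondrial peaks on their own chromosome, and mitochondrial tRNA genes were not counted apart. The shares therefore do not show whether nuclear tRNA genes were marked above random placement in any library. The 597 HSC peaks without an MPP counterpart had a median −log10 q of 2.89, against 3.95 for those in both MPP libraries. They lay at a gene end in 14.6% (11.8 to 17.7), above the 3.26% of randomly placed HSC peaks and below the 37.7% of those in both. An MPP counterpart was present for 77.9% of HSC peaks in the lowest of 5 bins of −log10 q and 95.3% in the highest. In HSC peaks shared by all 3 libraries, the median pileup over background was 14.9 in HSC, 8.36 in MPP replicate 1 and 16.6 in MPP replicate 2. The lowest pileup called was 8.28, 3.48 and 5.55 times background in these libraries. Selection of the peaks as HSC calls raises the HSC median, so these medians do not rank the signal of the libraries.

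Of the tests that follow, the one on lower enrichment, the raised thresholds, the modelled medians, and the matched values of gene families and without Hspe1 were chosen after the result was seen, and those on MYC targets were set after the plain counts of marked MYC targets were seen but before the matched values. The HSC list is shorter than either MPP list, and the tables exclude none of the 3 explanations weighed. Lower depth stays open. Thinning MPP replicate 1 to the HSC depth gave 2.39 times the HSC peaks observed with the weakest HSC call as threshold. Only 58 HSC peaks had the lowest pileup. With the 25th percentile it gave 0.99, while replicate 2 gave 3.55 and 2.86. The control, replicate 1 thinned to replicate 2, fell from 0.93 to 0.40, so the procedure has no fixed value for equal libraries. The 0.99 therefore does not show that depth suffices. Replicate 1 gave more in HSC than in the control at all 4 thresholds: 2.39, 1.46, 1.21 and 0.99 against 0.93, 0.58, 0.50 and 0.40. That order points away from depth alone, but with 1 HSC library and 1 control pair it does not settle the question. Fewer RXRA sites in HSC cannot be told apart from a weaker assay, because the HSC library used 10000 cells and the MPP libraries 50000, and expected over observed MPP peaks with an HSC counterpart ranged from 1.34 to 4.62 with Poisson draws and was 5.02 for replicate 2 with binomial thinning. Lower enrichment in HSC stays open too, since the MPP libraries differ: across bins the factor on signal that gave the observed share varied by 1.06 to 1.19 times over 4 thresholds for replicate 2, below the 1.38 to 1.71 of evenly absent sites in simulation, but by 1.15 to 1.46 times for replicate 1, where absent sites gave 1.07 to 1.20. At MPP replicate 2 peaks found in HSC the median HSC signal was 14.9, against 11.6 modelled with 1 factor and 14.9 with absent sites, and at the 25th percentile 16.6, 16.6 and 18.2; for replicate 1 it lay above both models at every threshold, as in the control (12.9 against 7.40 and 8.32), so the medians do not decide it.

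The 40 HSC peaks of highest fold recur in both MPP libraries. If reads piled up at repeats, whatever the antibody, these peaks would lie at gene ends less often than other peaks, and they did, in 7.5% against 36.6%. This is consistent with such pile-up, which may include the peaks at Wls, Oasl1 and Lars2. A control antibody library and the genome sequence were not used here, so repeats were not examined directly, and no biological explanation was tested.

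MYC target genes were marked more often than random lists in all 3 libraries. For HSC, a general preference for ends bound in every library is argued against. Of the 36 MYC targets marked in both MPP libraries 16 were marked in HSC, at percentile 99.8 of lists matched on MPP fold (median 8). The MYC list was the 1 list of 20 above the central 95%, but lists with 1 gene could not reach that bound. The stromal list stood at 80.9 with its only gene marked, so that count does not show that the MYC targets stand alone. Without Hspe1, which shares a peak with Hspd1, the MYC targets stood at 99.7 among lists matched on MPP fold. Ribosomal protein genes, a stand-in for highly transcribed genes, fell from 99.98 to 69.4 in that comparison. Of their 22 genes marked in both MPP libraries 6 were marked in HSC (27.3%, 10.7 to 50.2, matched median 4). That interval overlaps the one of the MYC targets (44.4%, 27.9 to 61.9), so this short list cannot exclude high transcription. Genes of mitochondrial ribosomes, initiation factors and aminoacyl-tRNA synthetases fell from 99.8, 98.6 and 98.3 to 69.2, 61.7 and 46.9. Against lists matched on gene length the MYC targets stood at 100 in every library. In MPP a general preference stays open, since ribosomal protein and oxidative phosphorylation genes also stood at percentile 99.9 or above. With the nearest gene end within 50 kb these 2 lists fell to 94.2 and 88.2 in MPP replicate 1, where the MYC targets stood at 99.2. In replicate 2 they stayed at 99.98 and 98.9. At equal list length both lay within the central 95% in both MPP libraries. Binding of RXRA at MYC target genes in HSC may account for the excess there, as a hypothesis drawn from these same data and not tested here. GC content and a control antibody were not examined and stay open.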
